A study of Mus musculus with 4 samples.

How the data were processed

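HIT-seq maps the binding of a chromatin protein through the integration sites of an HIV-based vector. Per the labels' protocols, Psip1-null mouse embryonic fibroblasts (strain C57BL/6) were nucleofected with plasmids for TAF3 fused to the integrase-binding domain of LEDGF, left to recover for 24 to 36 h, sorted for GFP, and infected with 500 ng of a pseudotyped luciferase vector in 8 µg/mL polybrene. Cells were harvested after 48 to 72 h. Genomic DNA (10 µg) was sheared to about 500 bp, vector junctions were amplified by linker-mediated nested PCR, libraries were amplified for 15 cycles, and read pairs of 108 nt were sequenced. PCR reads without molecular identifiers are not independent molecules, so distinct positions and not reads were counted, and all intervals cover counting error and variation along the genome only.

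The authors deposited 1 list of integration sites per library as a 9-column BED file. Per the file headers, the lists hold integration sites from paired-end reads. Per the submitters' processing notes, the genome build was mm9 and MACS 1.4.2 was used, with no role given for it. The aligner, the filters and the rule for joining reads into a site are not given in the sources used here. The score column that the authors deposited is 0 in every line and was not used. A whole number that follows the read name in each line was taken as the number of reads of the site, from its values only; its minimum is 2 in every list, so sites with fewer are not listed. The read names show that Full WT came from another instrument and flow cell than the other 3 libraries, which were 3 lanes of 1 flow cell.

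The junction was taken as the 5′ end of the listed strand and is printed 1-based. That end recurred in 329 coordinates of Full WT, 392 of Full M880A, 705 of PHD WT and 459 of PHD M880A, and the other end in 153, 11, 47 and 22. The counts of the ends thus lay closest in Full WT, and the reason was not tested. Lines with the same chromosome, strand and junction were collapsed, which removed 354, 401, 722 and 472 lines. Groups were taken from the sample characteristics. Each group has 1 library, so no comparison has a replicate check, and no p-value across regions is given.

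Promoter, gene body, CpG island and gene list comparisons (19 lists) had been planned before the data were examined. They were not analysed here, since no genome or annotation of mm9 was used, and positions were not converted to another build. The planned comparisons that need coordinates only became the main ones: self-clustering, proximity between libraries, chromosome shares and windows of 100 kb in place of genes. For the case without an annotation, the rule fixed before the data were examined named the 10 fullest windows, taken here per library. The rule for genes (per comparison, the 10 highest and the 10 lowest ratios of site shares with 0.5 added to each count, among those with at least 10 sites over both libraries) was carried over to windows after the data had been seen. The text gives a part of each set and summarises the rest.

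For self-clustering, proximity, foci and neighbour distances, every library was thinned at random to the 22486 sites of the smallest, and these shares are means of 10 draws. Windows, chromosome shares and identical positions used all sites. Self-clustering is the percent of sites with another site of the library within 1000 bp on either strand. Proximity is the percent of sites of a library with a site of another within 1000 bp. Backgrounds came from uniform placement between the first and last site of each chromosome (2570 Mb in all) and from moving every site at random by up to 50 kb. In self-clustering all sites were moved, and in proximity those of the second library. The 95% intervals come from 2000 resamples of 10 Mb blocks, with the same blocks in both libraries of a ratio. Window and chromosome ratios have exact conditional binomial intervals, and shares of sites per chromosome have Wilson intervals. A fold against a library with 0 sites, written with "at least", sets that library at a floor of 3 sites. It covers no counting error, so the exact interval printed beside it can reach a smaller fold. Foci, the share of 5 kb neighbours within 1 kb, ratios of self-clustering, and the matches on opposite strands were chosen after the data had been seen.

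The code was tested on simulated data. Planted neighbour shares were recovered exactly, the ratio interval held 1 in 95 of 100 comparisons of random equal parts of the PHD WT sites, and the window interval held the true ratio in 96.5% of simulated windows. Such parts have the same crowding, so the ratio interval was not checked for libraries with unlike crowding. Alternatives were neighbours within 5000 bp, merging of same-strand positions within 10 bp, a minimum of 10 reads, autosomes only, identical positions of other libraries left out, the mean number of neighbours, and shares divided by those of the moved sites. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.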

Results

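Integration sites of an HIV-based vector were mapped genome-wide in mouse embryonic fibroblasts that lack Psip1, the gene of LEDGF/p75, the host protein that normally tethers HIV integrase to chromatin. The cells were transfected with fusions of TAF3, a subunit of the general transcription factor TFIID, to the integrase-binding domain of LEDGF, so that integration can mark places where the fusion protein is bound. TAF3 carries a PHD finger, a small zinc-binding domain that recognises histone H3 trimethylated on lysine 4, a mark of active promoters. The design crossed the length of the fusion (full-length TAF3, here Full, or the PHD domain alone, here PHD) with its sequence (wild type, WT, or the M880A substitution). It asks where in the genome each form of TAF3 is bound, and how this depends on the rest of the protein and on residue 880.

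Each of the 4 combinations was represented by 1 library, so no difference below has a replicate check, and every test compares these libraries and not the conditions. The Full WT list held 22486 distinct integration positions, the Full M880A list 39292, the PHD WT list 25363 and the PHD M880A list 34888. The numbers attached to the sites, taken as reads, summed to 2119983, 3651264, 2228958 and 2085037 in the same order, with medians of 40, 23, 28 and 22 per listed site and a minimum of 2 in each list. Sites lay on 20 chromosomes, the 19 autosomes and X, and were evenly divided between the strands, with between 49.9% and 50.3% on the plus strand. The Full WT library was sequenced on a flow cell of its own, and the other 3 libraries shared a flow cell. For self-clustering, proximity, foci and neighbour distances, each library was first thinned to 22486 sites, so that these shares are not set by the number of sites. Windows, chromosome shares and identical positions used all sites, so counts in them depend on the length of the list. Intervals are 95% intervals from resampling 10 Mb blocks of the genome, and they cover variation along the genome and counting error only.

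The first comparison asked how the PHD domain alone was distributed with and without M880A. The PHD WT sites were crowded into small regions and the PHD M880A sites were dispersed. Of the PHD WT sites, 65.4% (63.9 to 66.9) had another PHD WT site within 1 kb, against 6.19% (5.71 to 6.73) of the PHD M880A sites, a ratio of 10.6 (9.79 to 11.4). Uniform placement of the same number of sites on their own chromosomes gave 1.88% and 1.76%. Moving every site at random by up to 50 kb, which keeps the broad regional preference and removes the fine positions, gave 11% and 2.71%. The PHD WT share was 34.7 times the first background and 5.94 times the second, and the PHD M880A share 3.51 and 2.29 times. Of the PHD WT sites, 16.3% (15.2 to 17.5) lay within 1 kb of a PHD M880A site, 3.96 times the share after PHD M880A sites were moved by up to 50 kb. In the other direction 6.60% (6.09 to 7.24) of the PHD M880A sites lay near a PHD WT site, 1.68 times the share after PHD WT sites were moved. Both libraries came from the same flow cell. The ratio of 10.6 was 4.42 (4.25 to 4.61) with neighbours counted within 5 kb and 16.1 (14.3 to 18.3) among sites with at least 10 reads. It was 2.60 (2.36 to 2.84) when each share was divided by that of its moved sites, a background that by construction rises with the crowding of the library.

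**Figure D1:**
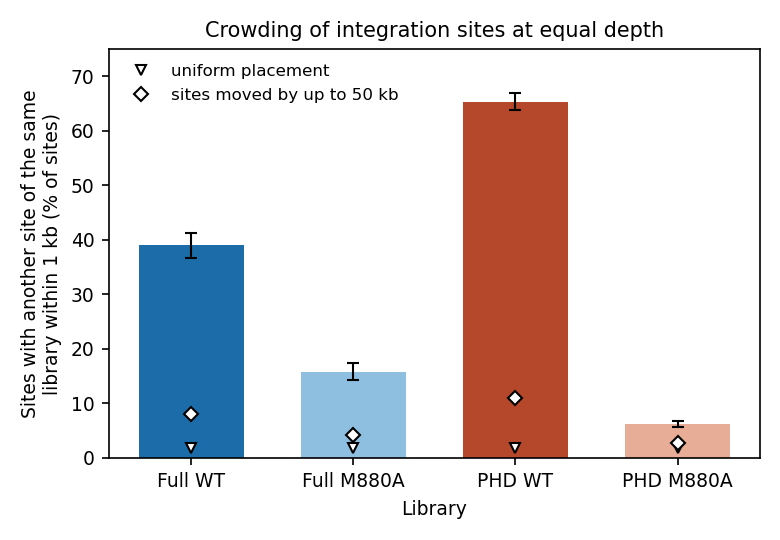
Share of sites (percent, y axis) with another site of the same library within 1 kb, for the 4 libraries on the x axis, each thinned to 22486 sites; bars are the mean of 10 draws, error bars the 95% block interval, triangles uniform placement and diamonds sites moved by up to 50 kb. The order is PHD WT (65.4%), Full WT (39.1%), Full M880A (15.8%) and PHD M880A (6.19%).

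The crowded PHD WT regions were short. When at least 5 sites with gaps of at most 1000 bp were called a focus, the thinned PHD WT library had on average 1019 foci with a median width of 1312 bp, and the thinned PHD M880A library 11.2. The PHD WT foci, with 500 bp added on each side, covered 0.0977% of the span between the outermost sites. They held 15.1% (13.4 to 16.7) of the Full WT sites, 5.76% (5.02 to 6.61) of the Full M880A sites and 2.15% (1.81 to 2.55) of the PHD M880A sites. Those shares were 154, 59.0 and 22.0 times the covered share. Among all neighbours that PHD WT sites had within 5 kb, 63.8% (62.3 to 65.4) lay within 1 kb, compared with 32.9% (31.4 to 34.6) in PHD M880A, a difference of 31 percentage points (28.8 to 33.0). The density of PHD WT neighbours was 1.87 per kb at distances up to 100 bp, 0.548 per kb between 1000 and 1500 bp and 0.0515 per kb between 3000 and 5000 bp. The PHD M880A density was 0.110 per kb up to 100 bp, 0.0259 per kb between 1000 and 1500 bp and 0.0179 per kb between 3000 and 5000 bp. Uniform placement gave 0.00845, 0.00909 and 0.00902 per kb at these distances. Between 100 and 200 bp the density was already 0.0343 per kb in PHD M880A, and 1.65 per kb in PHD WT. Merging same-strand positions within 10 bp lowered self-clustering from 6.19% to 4.88% in PHD M880A and from 65.4% to 64.3% in PHD WT. Positions a few bp apart thus make up a part of the short-range PHD M880A values.

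**Figure D2:**
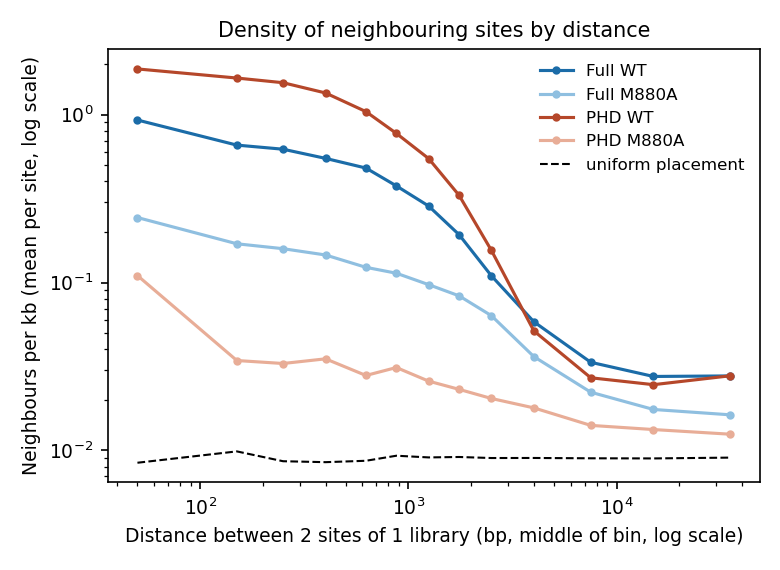
Mean number of neighbouring sites per kb (y axis, log scale) against the distance between 2 sites of 1 library (x axis, bp, log scale) for the 4 thinned libraries and for uniform placement. The PHD WT curve starts at 1.87 and the Full WT curve at 0.929 per kb, and both are at 0.0278 per kb between 20000 and 50000 bp; the PHD M880A curve runs from 0.110 to 0.0125 per kb.

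The 5 PHD WT foci with the most sites were chosen after their values were seen (coordinates are mm9). On chromosome 5, positions 143575291 to 143578643 held 31 PHD WT, 11 Full WT, 19 Full M880A and 5 PHD M880A sites. On chromosome 17, positions 24855855 to 24861200 held 30, 17, 10 and 3 sites in the same order. On chromosome 11, positions 6371858 to 6375412 held 25, 7, 7 and 6 sites, and positions 120094644 to 120099197 held 25, 13, 15 and 0. On chromosome 3, positions 58220676 to 58224720 held 24, 4, 6 and 8 sites. These counts are not thinned, and the PHD M880A list was longer than the PHD WT list.

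In windows of 100 kb, 1056 windows held at least 10 sites over the PHD pair. The share of sites was higher in PHD WT in 481 of them and lower in 2, by exact conditional intervals that exclude 1 and are not adjusted for the number of windows. Windows entered by their unthinned total over the pair, so a crowded library can bring in the windows where it is high. The PHD M880A list was the longer one, and the net effect of this rule was not computed. The imbalance may thus follow in part from the crowding given above. The 10 windows with the highest ratios held no PHD M880A site. Among them, the chromosome 11 window from 69800001 to 69900000 held 28 PHD WT sites, a share at least 12.8-fold higher when 3 sites are taken as the floor of the PHD M880A library, with an exact interval of the ratio from 9.77. On chromosome 8, positions 87500001 to 87600000 held 22 PHD WT sites, at least 10.1-fold higher by the same floor (interval from 7.54, and from 2.46 among sites with at least 10 reads). On chromosome 4, positions 124300001 to 124400000 held 16, at least 7.34-fold higher (from 5.30). The other 7 windows had between 11 and 15 PHD WT sites. Of the 10 windows with the lowest ratios, 2 had an interval below 1. One was on chromosome 1 from 162900001 to 163000000, with 3 PHD WT and 18 PHD M880A sites (ratio of shares 0.260, 0.0433 to 0.785), and 0.173 (0.00281 to 0.813) among sites with at least 10 reads. The other was on chromosome 17 from 39900001 to 40000000, with 0 and 10 sites, at least 2.42-fold lower in PHD WT (interval of the ratio up to 0.614), and its interval held 1 among sites with at least 10 reads. The remaining 8 had 2 or 3 PHD WT and 8 to 10 PHD M880A sites, and their intervals held 1.

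The same question for the full-length protein gave a difference in the same direction. Of the Full WT sites, 39.1% (36.7 to 41.3) had a neighbour of their own library within 1 kb, against 15.8% (14.3 to 17.3) of the Full M880A sites, a ratio of 2.47 (2.36 to 2.61). Moving the sites by up to 50 kb gave 7.96% and 4.20%, so that the Full WT share was 4.91 times and the Full M880A share 3.76 times its own background. The ratio of these folds was 1.31 (1.23 to 1.39). Of the Full WT sites, 24.9% (23.0 to 26.8) lay within 1 kb of a Full M880A site, 4.43 times the share after Full M880A sites were moved, and 17.2% (15.6 to 18.8) of the Full M880A sites lay near a Full WT site, 3.20 times its moved background. The thinned Full WT library had 445 foci of at least 5 sites with a median width of 1461 bp, and the thinned Full M880A library 103 with a median width of 1662 bp. The share of 5 kb neighbours that lay within 1 kb was 53.9% (52.0 to 55.8) in Full WT and 39.2% (37.9 to 40.5) in Full M880A, a difference of 14.7 points (13.1 to 16.5). Because Full WT was the only library on its flow cell, flow cell and sequence cannot be told apart in this pair.

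Of 976 windows of 100 kb with at least 10 sites over the Full pair, the share was higher in Full WT in 138 and lower in 6. These intervals are not adjusted for the number of windows, so some exclude 1 by chance, and the 6 may be of this kind. Windows entered by their unthinned total over the pair. Full WT was the more crowded library, but the Full M880A list was longer. Which of them this rule favours was not computed, so how far the imbalance follows from it stays open. The highest ratio was on chromosome 14 from 56200001 to 56300000, with 11 Full WT sites and 1 Full M880A site (ratio 13.4, 2.79 to 827), and it was 8.58 (1.62 to 538) among sites with at least 10 reads. Chromosome 17 from 45700001 to 45800000 had 19 and 4 sites (7.57, 2.76 to 33.5), and chromosome 11 from 97600001 to 97700000 had 17 and 4 (6.80, 2.42 to 30.3). At the other end, windows on chromosome 2 from 152700001 to 152800000 and on chromosome 4 from 144800001 to 144900000 held no Full WT site and 10 Full M880A sites each, at least 1.91-fold lower in Full WT by the floor of 3 sites (interval of the ratio up to 0.780). Chromosome 1 from 88300001 to 88400000 held 4 Full WT and 28 Full M880A sites (0.276, 0.0636 to 0.714), with 1 site in each PHD library. The interval of this last ratio held 1 among sites with at least 10 reads.

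The size of the WT to M880A difference was not equal in the libraries of the 2 lengths. Full WT was the only library on its flow cell, so length and flow cell cannot be told apart here. The ratio of WT to M880A crowding was 10.6 for PHD and 2.47 for Full, and the ratio of these ratios was 4.27 (3.95 to 4.63). With the mean number of neighbours in place of the share, which has no upper limit, the ratios were 31.1 and 3.74 and their ratio was 8.32 (7.01 to 9.87). With neighbours counted within 5 kb the ratio of ratios was 2.41 (2.31 to 2.52), and with each share divided by that of its moved sites it was 1.99 (1.83 to 2.18).

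With the WT sequence, the comparison of Full with PHD asked whether the PHD domain alone reached the places of the whole protein. Of the PHD WT sites, 54.4% (52.3 to 56.4) lay within 1 kb of a Full WT site, 28.2 times the value for uniform placement (1.93%) and 5.95 times that after moving Full WT sites by up to 50 kb (9.13%). Of the Full WT sites, 40.2% (38.2 to 42.2) lay within 1 kb of a PHD WT site, against 1.91% and 9.16%. The thinned Full WT foci held 12.4% (10.6 to 14.4) of the PHD WT sites on 0.0448% of the span. Crowding itself was lower in Full WT than in PHD WT, with a ratio of 0.597 (0.571 to 0.623). Of the neighbours within 5 kb, 53.9% lay within 1 kb in Full WT and 63.8% in PHD WT, a difference of -9.90 points (-11.8 to -8.08). The libraries lay on different flow cells.

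**Figure D3:**
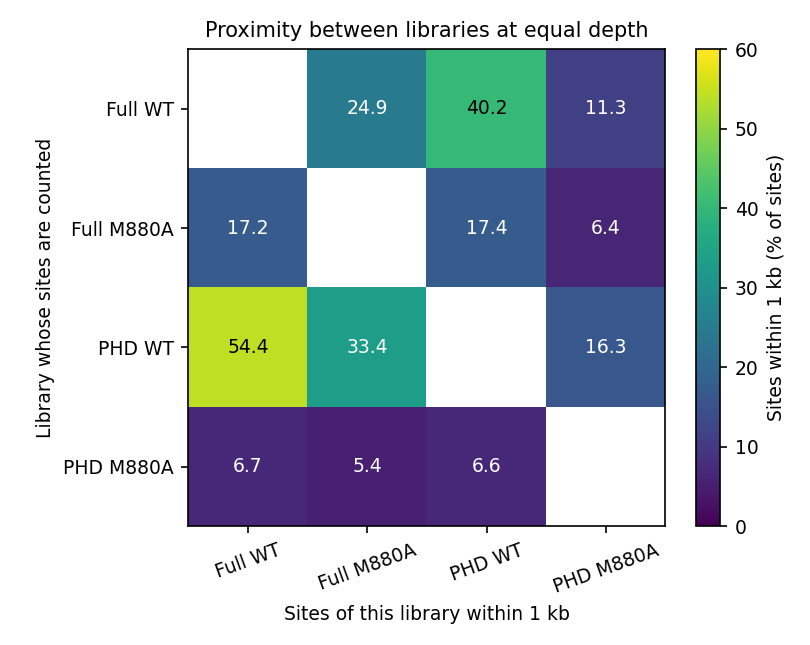
Share of the sites of each library (rows) within 1 kb of a site of another library (columns), in percent, with all libraries thinned to 22486 sites; colour and number give the same value and the diagonal is left empty. The highest values are those between PHD WT and Full WT (54.4% and 40.2%) the PHD M880A row lies between 5.36% and 6.66%, and the value of Full M880A near PHD M880A is 6.37%.

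Of 1160 windows of 100 kb with at least 10 sites over the pair, the share was higher in Full WT in 15 and lower in 79. Without adjustment for the number of windows, the 15 may arise by chance. Entry by the pair's total can favour PHD WT, which was more crowded and had the longer list. The imbalance may follow in part from this rule, whose effect was not computed. In the window of chromosome 17 from 46700001 to 46800000, Full WT had 11 sites and PHD WT 2 (ratio 5.19, 1.35 to 57.6). In that of chromosome 15 from 102500001 to 102600000, Full WT had 9 sites and PHD WT 2 (4.29, 1.05 to 48.3), with 21 in Full M880A and 0 in PHD M880A. Both of these intervals held 1 among sites with at least 10 reads. In the opposite direction, chromosome 2 from 84400001 to 84500000 had 2 Full WT and 20 PHD WT sites (0.138, 0.0128 to 0.464). Windows on chromosome 2 from 13900001, chromosome 6 from 7700001 and chromosome X from 149900001 held 0 Full WT and 10 PHD WT sites each, at least 2.96-fold lower in Full WT (interval of the ratio up to 0.503). The 10 fullest windows of Full WT had 5 in common with those of PHD WT, 5 with Full M880A and 1 with PHD M880A. Those of PHD WT had 4 in common with Full M880A and 1 with PHD M880A, and the M880A libraries had 2 in common.

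The last comparison set the M880A forms of both lengths against each other, on 1 flow cell. Crowding was higher in Full M880A than in PHD M880A, 15.8% against 6.19%, a ratio of 2.55 (2.32 to 2.81), which was 1.70 (1.61 to 1.79) with neighbours counted within 5 kb and 1.64 (1.52 to 1.78) with each share divided by that of its moved sites. Proximity to the WT sites also differed: 17.4% (16.1 to 18.9) of the Full M880A sites lay within 1 kb of a PHD WT site, against 6.60% (6.09 to 7.24) of the PHD M880A sites, a ratio of 2.64 (2.47 to 2.82). For proximity to Full WT the ratio was 2.58 (2.42 to 2.75). Both differences were smaller against the shares after the WT sites were moved. Near PHD WT the folds were 3.11 for Full M880A and 1.68 for PHD M880A, and near Full WT 3.20 and 1.84. Of the Full M880A sites, 6.37% (5.85 to 6.93) lay within 1 kb of a PHD M880A site, 3.46 times uniform placement and 2.15 times the share after PHD M880A sites were moved (19.2% within 5 kb). Of the PHD M880A sites, 5.36% (4.88 to 5.91) lay within 1 kb of a Full M880A site and 6.66% (6.08 to 7.36) within 1 kb of a Full WT site, 1.86 and 1.84 times the shares after the sites of the other library were moved.

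Of 870 windows with at least 10 sites over the M880A pair, the share was higher in Full M880A in 145 and lower in 5. Again the intervals are not adjusted, and the 5 may arise by chance. Entry by the pair's total can favour Full M880A, which was more crowded and had the longer list. The imbalance may follow in part from this rule, whose effect was not computed. The windows of chromosome 8 from 87500001 to 87600000 and of chromosome 15 from 102500001 to 102600000 held 22 and 21 Full M880A sites and no PHD M880A site, at least 6.51-fold and 6.22-fold higher (intervals from 4.86 and 4.62). Chromosome 11 from 69800001 to 69900000 held 16 and 0, at least 4.74-fold higher (from 3.42). In the other direction, chromosome 1 from 162900001 to 163000000 had 4 Full M880A and 18 PHD M880A sites (0.216, 0.0486 to 0.599), and chromosome 16 from 23100001 to 23200000 had 3 and 12 (0.249, 0.0402 to 0.823), with 0.134 (0.00215 to 0.657) among sites with at least 10 reads.

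The fullest windows of the genome were shared by several libraries. In the chromosome 11 window from 120000001 to 120100000 there were 49 PHD WT, 37 Full WT, 46 Full M880A and 8 PHD M880A sites, which is 19.3, 16.5, 11.7 and 2.29 per 10000 sites of each library. Chromosome 19 from 5400001 to 5500000 held 41, 45, 41 and 11 sites (16.2, 20, 10.4 and 3.15 per 10000), and chromosome 5 from 143500001 to 143600000 held 36, 32, 45 and 7 (14.2, 14.2, 11.5 and 2.01 per 10000). Chromosome 15 from 98700001 to 98800000 held 33, 39, 26 and 5 sites. In contrast, chromosome 19 from 5800001 to 5900000 held 26 PHD WT, 35 Full WT, 44 Full M880A and 35 PHD M880A sites, between 10.0 and 15.6 per 10000 in all 4 libraries, and this was the fullest window of PHD M880A. The fullest Full M880A window was on chromosome 10 from 79600001 to 79700000, with 56 Full M880A, 25 Full WT, 15 PHD WT and 3 PHD M880A sites.

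**Figure D4:**
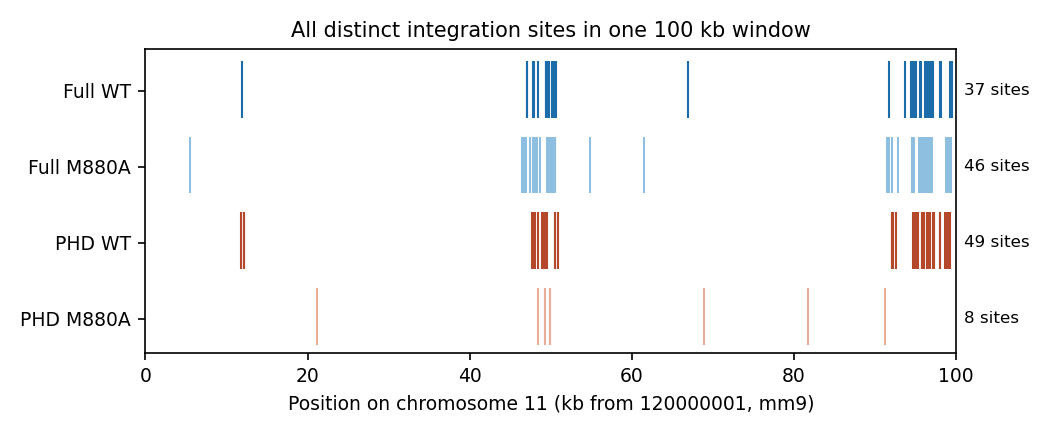
Positions of all distinct sites (not thinned) of the 4 libraries, 1 row each, in the 100 kb window of chromosome 11 that starts at 120000001 (x axis, kb from the window's start, mm9); each line is 1 site and the number at the right counts them. The window holds 37 Full WT, 46 Full M880A, 49 PHD WT and 8 PHD M880A sites. The stretch from 120094644 to 120099197 in it holds 13, 15, 25 and 0 of them.

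Whole chromosomes differed less than short regions. Relative to PHD M880A, PHD WT had a higher share of its sites on 7 chromosomes and a lower share on 9, by exact conditional intervals that exclude 1 without adjustment. The highest ratio was on chromosome 17, with 5.54% (5.26 to 5.82, Wilson) of PHD WT and 4.10% (3.89 to 4.31) of PHD M880A sites, a ratio of 1.35 (1.25 to 1.46). Chromosomes 11 (1.23, 1.16 to 1.30), 7 (1.22, 1.13 to 1.32) and 19 (1.22, 1.12 to 1.34) followed, and chromosomes 11, 17 and 19 are known as gene-rich. The lowest ratios were on chromosomes 1 (0.798, 0.748 to 0.850), 13 (0.816, 0.751 to 0.886) and X (0.829, 0.768 to 0.894). In the Full pair, 5 chromosomes were higher and 4 lower in WT, with 1.20 (1.12 to 1.29) on chromosome 17, 1.14 (1.07 to 1.21) on chromosome 11 and 0.801 (0.737 to 0.870) on X. Between the WT libraries the intervals of 19 chromosomes held 1, and X had a lower share in Full WT (0.864, 0.789 to 0.947).

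**Figure D5:**
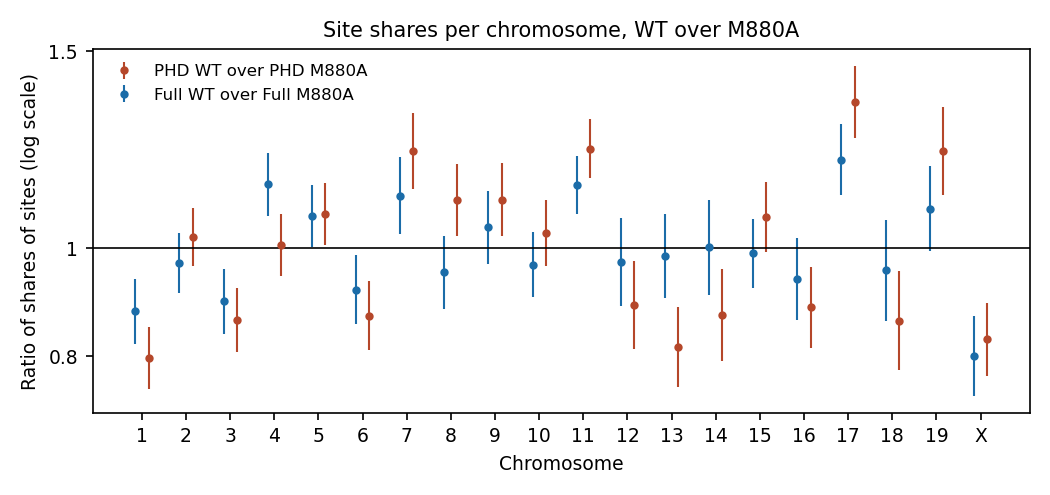
Ratio of the share of sites per chromosome (y axis, log scale), WT over M880A, for the PHD pair and the Full pair (x axis, chromosome); bars are exact conditional 95% intervals that cover counting error. Chromosomes 11 and 17 lie above 1 in both pairs (1.23 and 1.35 for PHD, 1.14 and 1.20 for Full), and chromosome 1 (0.798 and 0.878) and X (0.829 and 0.801) lie below 1 in both.

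Some positions were hit in more than 1 library. Full WT and PHD WT shared 200 identical positions on the same strand, where uniform placement gives 0.120, and offsets of 10 to 30 bp gave a mean of 12.8. Full M880A shared 104 with PHD WT and 67 with Full WT. PHD M880A shared 46 with Full WT, 40 with PHD WT and 25 with Full M880A. HIV integration duplicates 5 bp of target DNA, so a site used in both orientations appears as junctions on opposite strands 5 bp apart. Full WT and PHD WT had 143 such opposite-strand matches, Full WT and Full M880A 69, and Full M880A and PHD WT 97, against means of 12.5, 6.02 and 8 at neighbouring offsets. The ratio of the opposite-strand excess to the same-strand excess was 0.697 (0.548 to 0.878) for Full WT with PHD WT and 0.287 (0.126 to 0.519) for Full WT with PHD M880A, by Poisson intervals. In the other 4 pairs the interval held 1, with 1.02 (0.699 to 1.49) for Full WT and Full M880A, 0.934 (0.685 to 1.27) for Full M880A and PHD WT, 0.597 (0.272 to 1.18) for the M880A libraries and 0.720 (0.415 to 1.19) for the PHD libraries.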

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

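The tests of flow cell, of cross-talk, of broad regions, of regions open whatever the fusion and of identical positions were chosen after the results were seen, as were the ratio of ratios and its alternatives.

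The WT to M880A ratio of crowding was 4.27 times larger for PHD than for Full, with an interval that excluded 1, and 1.99 times (1.83 to 2.18) larger when each share was divided by that of its moved sites. False extra sites with fewer than 10 reads beside true ones are argued against as the whole source of the higher crowding of Full M880A. Its ratio to PHD M880A was 3.25 (2.87 to 3.74) among sites with at least 10 reads. The test does not reach false sites with more reads. Reads summed to 3651264 in Full M880A and 2085037 in PHD M880A, and the cut also leaves fewer sites per library. A Full M880A library that holds molecules of a WT library stays open, as neither test of it decides: in 0 of 2841 windows was the share of Full M880A above that of each other library by one-sided exact tests at p under 0.001, but a window had to pass 3 such tests and no library passed its limit, and 8.63% (5.86 to 12.2) of the 336 foci among all 39292 Full M880A sites held no WT site, but the reference of 11.2%, from random equal parts of Full WT, was searched against fewer sites. The flow cell of Full WT cannot be told apart from its sequence, since 1 library was run on it. A difference between the 2 lengths of the protein in what they bind stays open and was not tested.

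Cross-talk between libraries alone is argued against as the cause of the proximity of Full WT and PHD WT sites. These libraries shared 200 identical positions, among 25363 PHD WT sites. Leaving out identical positions could thus hardly lower the share of PHD WT sites within 1 kb of a Full WT site. It was then 53.5% (51.4 to 55.6), which adds no separate support. A preference for the same broad regions alone would give the 9.13% seen after sites were moved by up to 50 kb, below the observed 52.3 to 56.4. Short regions open to integration in these cells whatever the fusion are argued against as the whole cause, since PHD WT sites lay near Full WT sites 8.16 times (7.57 to 8.76) as often as PHD M880A sites did. Against moved Full WT sites the folds were 5.95 for PHD WT and 1.84 for PHD M880A, so a part played by such regions stays open, and no library without a fusion protein was analysed here.

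Identical positions in different libraries were weighed in the same way. Cross-talk would give matches on the same strand, whereas reuse of a position in both orientations would give as many matches on opposite strands 5 bp apart. The ratio of the opposite-strand excess to the same-strand excess was 0.697 (0.548 to 0.878) for Full WT and PHD WT and 0.287 (0.126 to 0.519) for Full WT and PHD M880A. In these 2 pairs this argues against cross-talk alone and against recurrent use alone, and what lowers the ratio stays open. Both hold Full WT, which was sequenced on another instrument and flow cell than its partners. So does the pair of Full WT and Full M880A, where the ratio was 1.02 (0.699 to 1.49). Its interval overlapped that of Full WT and PHD WT, and not that of Full WT and PHD M880A. No difference between pairs was tested, so a part played by the flow cell of Full WT stays open. In the other 4 pairs the ratio ran from 0.597 to 1.02 with intervals that held 1, so recurrent use alone was not argued against there.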

How the results depend on the processing

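No planned comparison that needs genes, start sites, CpG islands or random positions in the genome sequence was run, nor were their alternatives, because no genome or annotation of mm9 was used. The 4 ratios of crowding and the ratio of ratios kept their direction and intervals that exclude 1 under all 7 alternatives. Alternatives to these ratios, to foci and to windows, and those to shares not marked planned below, were chosen after seeing the data. Between shares divided by those of the moved sites and the mean number of neighbours, PHD WT over PHD M880A ranged from 2.60 to 31.1, Full WT over Full M880A from 1.31 to 3.74, Full M880A over PHD M880A from 1.64 to 3.69, Full WT over PHD WT from 0.826 to 0.443, and the ratio of ratios from 1.99 to 8.32. Shares, given for Full WT, Full M880A, PHD WT and PHD M880A, moved beyond their binomial interval as follows, and the cause was not tested beyond what the wider distance, the merging or the fewer sites bring by construction. Within 5000 bp (planned), crowding was 51.0%, 27.8%, 72.5% and 16.4%. Merging within 10 bp (planned) gave 37.7%, 14.5%, 64.3% and 4.88%. At least 10 reads, which leaves 16580 sites per library, gave 34.5%, 12.8%, 63.7% and 3.94%. Autosomes alone moved Full M880A to 16.4%, and leaving out identical positions moved Full WT to 38.3% and Full M880A to 15.3%. Proximity of Full WT to Full M880A, Full WT to PHD WT, PHD WT to PHD M880A and Full M880A to PHD M880A was 39.97%, 50.2%, 34.9% and 19.2% within 5000 bp (planned) and 21.7%, 38.4%, 14.2% and 5.30% with at least 10 reads. Leaving out identical positions (planned) moved Full WT to Full M880A to 24.2% and Full WT to PHD WT to 39.3%. With 3 instead of 5 sites per focus, PHD WT had 2278 foci, and they held 22.8% of Full WT, 8.67% of Full M880A and 3.09% of PHD M880A sites. Of 80 window ratios, 0 changed direction under merging, without identical positions or with at least 10 reads. In the last, 11 intervals came to hold 1 and 1 no longer did. The windows had been picked for extreme ratios, and the alternatives reused the same sites. A kept direction is thus weak support. No paired analysis was possible because each group has 1 library. Depth limits single windows: with fewer than 10 sites over a pair no ratio was read.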

Other observations

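The windows described here were singled out after their values were seen. On chromosome 2 from 30500001 to 30600000 there were 31 Full M880A, 6 Full WT, 2 PHD WT and 1 PHD M880A sites. On chromosome 10 from 79800001 to 79900000 there were 46, 20, 7 and 15.

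The 10 fullest PHD M880A windows held between 3 and 34 PHD WT sites. On chromosome 11 from 86300001 to 86400000 PHD M880A had 24 sites, with 19 in PHD WT, 13 in Full WT and 12 in Full M880A, and on chromosome 4 from 88500001 to 88600000 it had 18, with 20, 4 and 10. On chromosome 1 from 162900001 to 163000000 it had 18, with 3, 9 and 4. Of the PHD M880A sites with a PHD M880A neighbour within 1 kb, 32.1% lay within 1 kb of a PHD WT site, and of those without, 4.92%.

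A hypothesis written before its test was that the crowded part of the Full M880A sites lies where PHD WT crowds. Full M880A sites with a Full M880A neighbour within 1 kb lay near a PHD WT site in 60.6% of cases, 4.11 times the value after PHD WT sites were moved by up to 50 kb, and those without a neighbour in 9.35%, 2.40 times. The ratio of these folds was 1.71 (1.59 to 1.86), above 1 as predicted. The test cannot decide the hypothesis, because it counted proximity to any PHD WT site, crowded or not. PHD M880A sites gave 2.25 (1.94 to 2.62). The higher fold of sites with a neighbour is thus not particular to the full-length protein, and short regions that favour integration in all libraries may contribute.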
